A study of Homo sapiens with 2 samples.

How the data were processed

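RNA from 2 cultures of LoVo cells was measured on 2 one-colour Agilent arrays, 1 array per group. LoVo is an established human colorectal cancer cell line. LoVo-P cells were stably transfected with a green fluorescent protein (AcGFP) vector carrying PRL-3, and LoVo-C cells with the vector alone, per the labels. PRL-3, encoded by PTP4A3, is a small phosphatase. Both lines were collected after 48 h of culture, ribosomal RNA was removed, and the RNA was amplified by random priming and labelled with Cy3, per the labels' protocols.

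The intensity values are those the scanner software wrote, deposited as they were: Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes, with its one-colour protocol and a probe design on build hg19, per the file headers. They are background-subtracted and spatially detrended brightness per spot on a linear scale, with a floor for spots at background, and they were not normalized between arrays before deposit. The other columns used, which the authors deposited in the same files, are the software's error of each intensity, the median brightness of spot and local background, and flags for spots well above background, saturated or outlying. The authors also deposited a table of processed log2 values of the same arrays. Its method is not given in the sources used here; its 2 columns have the same median of 5.26, and their sorted values lie at most 0.0527 apart, as quantile normalization leaves them. Scale and direction of that table were checked against the scanner values, with which the columns correlated at 0.998 (LoVo-C) and 0.997 (LoVo-P) across probes. How its background was treated is not stated. Over probes above background on both arrays, its differences correlated at 0.9987 with those of the scanner values. Their SD was 0.5831, against 0.5835 with quantile normalization of the scanner values here. The table thus lies close to that alternative and is no separate check of it. The headers of both scanner files record the same scan and different array positions, so slide and scan date do not separate the groups, while array position and group cannot be told apart.

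Each array carried 62903 spots. The comparisons used 60855 probes after spots with a non-uniformity or population outlier flag on either array were left out, which removed 69 probes. Control spots were left out, and so were the 60 probes named as negative controls. Spots of one probe were averaged on the log2 scale. The main scale was log2 of the processed intensity minus the array's own 75th percentile of it. Differences are LoVo-P minus LoVo-C, and a probe entered the counts when it was well above background on both arrays. A probe above background on one array only has a lower bound, taken against the higher of its own signal and the lowest signal well above background on the other array. Because flagged outlier spots were removed, the spot SDs are trimmed: the median SD of the 18 genes' probes was 0.0237 on the log2 scale, and 0.0348 with all spots kept.

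The files give a gene identity for few probes. The study's design text speaks of 20730 mRNA and 40173 long non-coding RNA transcripts, but 60904 probes carry only design numbers, so mRNA and long non-coding RNA were counted together and the planned counts of each were not made. Of the rest, 20 probes, each spotted 10 times per array, carry RefSeq accessions, and all 20 matched a symbol through a RefSeq gene table of assembly GRCh38.p14, used for names only. Of these genes 18 are described, and 2 are not reported here but stay in the counts over all probes. Another 12 control probes have GAPDH or PGK1 of human, mouse or rat in their names. PTP4A3 was not analysed here, so the labels were not checked against its level. Of 43 gene lists, fixed before the data were examined like the comparisons and the alternatives below, 38 had no member among the 18 genes and none reached the minimum of 5 (the highest was 3), so no list was described. The rule for named genes, fixed at the same time, was PTP4A3, then the 12 genes with the largest differences each way at or above the median level, then named long non-coding RNAs, one-array genes and members of the lists. With few named genes, the median level was taken over all probes above background. The rule then took 15 of the 20 genes, 13 of them among the 18, and its other parts named none. GRM4, H3-3A, PRMT1, EIF3D and MTX1 fell outside it and were added after their values were seen, to complete the 18. Of unnamed probes above background on both arrays, the 2 highest and 2 lowest are given by design number.

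With 1 array per group there is no replicate, so no test, p-value or count of significant genes between the groups was made. SDs are over spots of one array and measure within-array error only, not the spread between cultures, and the number of arrays limits the precision. For single-spot probes the software's own error was carried to the log2 scale. The counting step was tested on simulated data with 60855 probes: of 50 probes changed 3-fold, 98% were called at least 2-fold in the right direction. The share was 88% of 50 changed 4-fold, 88% of 50 changed 8-fold and 0% of 50 changed 1.5-fold. The probes changed 3-fold or more that were not called (1, 6 and 6) had fallen below background on an array. All changed probes were drawn from those above background on both real arrays, so the shares do not cover dimmer probes. None of 38634 unchanged simulated probes passed. The simulation held spot noise alone, with a fixed additive error. Its multiplicative part was the median spot SD of the repeated genes, with flagged spots left out. For real probes above background the software's combined error of a difference had a median of 0.207 on the log2 scale. The absence of false calls therefore says little about single-spot probes.

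The alternatives were normexp background correction (offset 50), quantile normalization, scaling to the median, the 75th percentile over probes above background on both arrays, a loess fit on level (span 0.3), the authors' values, flagged spots kept, no filter on dim probes, only probes above the median level, and thresholds of 1.5-fold and 4-fold. Normexp was run on the median spot signal, and the mean spot signal named in the plan was not used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, R 4.3.3 and limma 3.58.1 were used.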

Results

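Expression was profiled in LoVo colorectal cancer cells that overexpress the phosphatase PRL-3 (LoVo-P) and in cells carrying the empty vector (LoVo-C). Each group was represented by 1 array. Of 60855 probes, 38862 (63.9%) were well above background on the LoVo-C array and 38855 (63.8%) on the LoVo-P array, and 37262 were so on both. The median intensity was 36.8 units on the LoVo-C array and 39.7 on the LoVo-P array, and no spot was saturated. Of 360 spots of negative control probes, 51 (14.2%) were called well above background on the LoVo-C array and 49 (13.6%) on the LoVo-P array, and 5 of the 60 probes passed on every spot of both arrays.

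The first comparison concerned 18 genes that the arrays measure on 10 spots each. PGK1, the glycolytic enzyme phosphoglycerate kinase, was the 1 gene of the 18 that differed at least 2-fold, at 2.14 times the scaled LoVo-C signal on the LoVo-P array. ACTG1, which encodes cytoplasmic gamma-actin, was 1.30 times as high on the LoVo-P array. ARHGDIA showed the largest difference in the other direction and was 1.33 times as high on the LoVo-C array. GAPDH, the neighbouring glycolytic enzyme, differed by -0.06 on the log2 scale, with overlapping spots and a sign that depended on the normalization.

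PGK1 (NM_000291) had a log2 level of 2.25 ± 0.06 (SD, n = 10 spots) relative to the array's 75th percentile in LoVo-C and 3.35 ± 0.06 (SD, n = 10 spots) in LoVo-P. The difference was 1.1 with a spot-based SE of 0.03. Of the 1863 probes in the same band of signal, 56 (3.01%) were higher on the LoVo-P array by as much or more. In either direction, 110 (5.90%) differed by as much or more. ACTG1 (NM_001614) stood at 9.22 ± 0.03 in LoVo-C and 9.59 ± 0.02 in LoVo-P (SD, n = 9 spots each), a difference of 0.38 ± 0.01 (SE). Under 7 other ways of correcting or scaling the values, this difference lay between 0.35 and 0.56, a wider range than the spot-based SE. The difference of ACTG1 was larger than the spread between spots. Of the 1864 probes in its band of signal, however, 505 (27.1%) differed by as much or more in either direction. Of the same probes, 159 (8.53%) were higher on the LoVo-P array by as much or more. That band is wide and also holds dimmer genes such as ODC1, at 6.22 in LoVo-C. Among the 370 probes with a mean level of at least 8, a range that includes ACTG1, differences had a median of -0.17 and an SD of 0.23.

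ACTB, the gene of cytoplasmic beta-actin, differed by -0.10 ± 0.01 (SE, n = 10 spots each), and PFN1, the actin monomer-binding protein profilin, by -0.09 ± 0.01 (SE, n = 9 spots each). Both values changed sign with a level-dependent (loess) normalization, to 0.09 in each. ARHGDIA (NM_004309) stood at 7.12 ± 0.04 in LoVo-C and 6.71 ± 0.04 in LoVo-P (SD, n = 9 spots each), a log2 difference of -0.41 ± 0.02 (SE). That difference lay between -0.44 and -0.29 under 7 other ways of correcting or scaling the values. In the band of signal of ARHGDIA, the same wide band as for ACTG1, 442 of 1864 probes (23.7%) differed by as much or more in either direction. Of these probes, 309 (16.6% of the band) were lower on the LoVo-P array.

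Lower signals on the LoVo-P array were also recorded for RACK1, a ribosome-associated scaffold protein (-0.26 ± 0.01, SE), and for ODC1, ornithine decarboxylase of polyamine synthesis (-0.25 ± 0.01, SE). COX4I1, a subunit of cytochrome c oxidase, differed by -0.25 ± 0.01 and DYNLL1, a dynein light chain, by -0.17 ± 0.02 (SE). The 3 ribosomal protein genes measured had values of -0.12 for RPLP1, -0.20 for RPS18 and -0.13 for RPL10. The RPL10 probe was far dimmer, at 290 units in LoVo-C and 280 in LoVo-P. RPLP1 read 298709 and 291950 units, and RPS18 read 312132 and 288564. The spots of RPL10 overlapped between the arrays, and the sign of RPLP1 depended on the normalization. With loess, the differences of COX4I1, RACK1 and ODC1 shrank to -0.07, -0.08 and -0.16, and those of DYNLL1 and RPS18 to -0.0052 and -0.0049. Ribosomal protein, actin and GAPDH transcripts have near-identical processed copies in the genome, so a probe for them can report more than one locus.

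The genes whose spots overlapped between the arrays included MTX1, a mitochondrial import protein (-0.02), EIF3D, a translation initiation factor subunit (-0.02), PRMT1, an arginine methyltransferase (-0.03), and H3-3A, a replication-independent histone H3 (-0.04). GRM4, a glutamate receptor gene, was the dimmest of the 18, at an intensity of 38.5 units in LoVo-C and 34.2 in LoVo-P, and its spots overlapped as well. In all, the spots of 11 genes separated the arrays without overlap, 2 of them higher on the LoVo-P array and 9 lower, of which PFN1, ACTB and RPLP1 changed sign with the normalization. Under the main scale and 7 other ways of correcting or scaling the values, 2 genes were always higher (PGK1 and ACTG1), 8 always lower (ARHGDIA, RACK1, ODC1, COX4I1, DYNLL1, RPS18, RPL10 and GRM4), and 8 had a sign that depended on the setting. Of the 18 genes, 12 had a mean level of at least 8. In that range 370 probes differed by an SD of 0.23 between arrays, against 0.58 over all 37262 probes. The 370 probes had a median difference of -0.17, and all 37262 one of -0.02. Scaling to 1 percentile leaves such a shift with level in place. Small negative values of bright genes, such as DYNLL1 (-0.17) and RPS18 (-0.20), cannot be told apart from it.

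**Figure D1:**
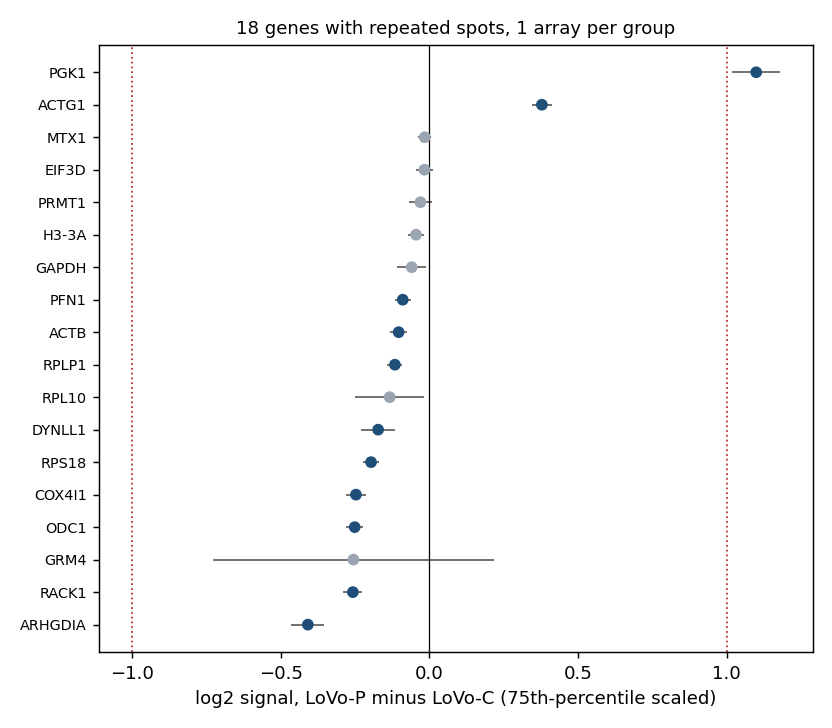
Log2 signal on the LoVo-P array minus that on the LoVo-C array for 18 genes measured on repeated spots. Points are differences of means over spots, bars are the SDs of both arrays' spots added in quadrature, dark points mark genes whose spots do not overlap between arrays, and dotted lines mark a 2-fold difference, which PGK1 alone passes at 1.1. The sign of 8 genes, ACTB, PFN1, RPLP1 and GAPDH among them, depends on the normalization.

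PGK1 was measured by further probes, the array's control probes named for PGK1 and GAPDH of human, mouse and rat, which hybridized here to human RNA. Of the 6 control probes named for PGK1, 5 were above background on every spot, and all 5 were higher on the LoVo-P array, by 0.73 to 1.37 on the log2 scale. Of the human probes, the one ending in 3 differed by 0.73 ± 0.02 (SE, n = 10 spots each), a ratio of 1.65, and the one ending in 5 by 1.25 ± 0.03 (SE, n = 10 spots each), a ratio of 2.38. Under 7 other ways of correcting or scaling the values, the former lay between 0.70 and 0.90 and the latter between 1.18 and 1.26. The 6 control probes named for GAPDH differed by -0.16 to 0.08 on the main scale. The human one ending in 3 changed sign with the normalization. The human one ending in 5 rose from 0.05 to 0.18 with loess and to 0.20 in the authors' values. The spread between PGK1 probes above background exceeded the spread between spots of any one of these, so the size of the PGK1 difference depended on the probe. Its direction was the same in the 6 probes above background.

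**Figure D2:**
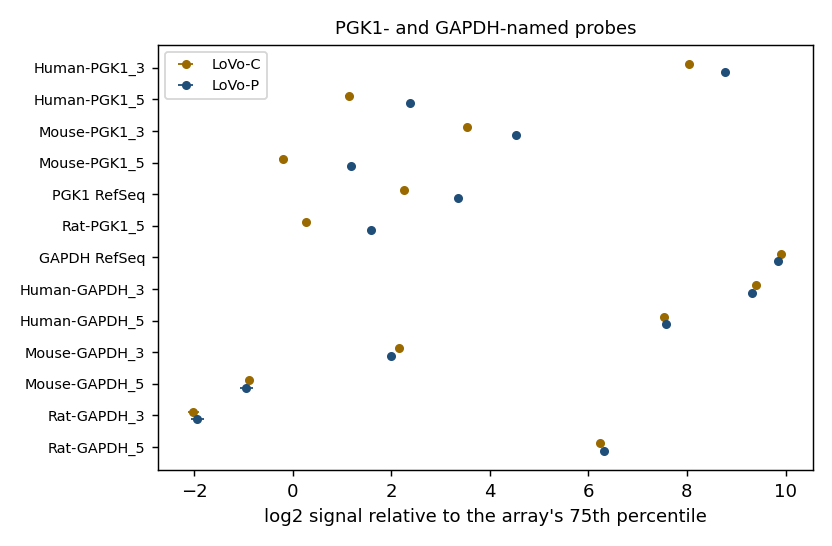
Log2 signal relative to each array's 75th percentile for the PGK1- and GAPDH-named probes above background on every spot of the LoVo-C array. Points are means and bars SDs over spots of 1 array; each PGK1 probe is higher on the LoVo-P array, by 0.73 to 1.37, and the GAPDH control probes differ by -0.16 to 0.08, with a sign that depends on the normalization for the human probe ending in 3.

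The second comparison covered all probes above background on both arrays, mRNA and long non-coding RNA together. Levels correlated across probes at 0.982 (Pearson) and 0.974 (Spearman); probes are not independent replicates. At least 2-fold higher signals on the LoVo-P array were found for 1154 probes (3.10%) and at least 2-fold lower signals for 1117 (3.0%). At 4-fold the numbers were 266 and 216, at 16-fold 53 and 24, and at 32-fold 22 and 10. The middle 90% of differences lay between -0.77 and 0.79. These are numbers of differences between 2 arrays, without a replicate check, and they fell to 601 and 631 under normexp background correction.

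Among probes with only a design number and above background on both arrays, the 2 with the largest differences each way were examined. Probe ASHGV40046319 had an intensity of 14.4 in LoVo-C and 7804 in LoVo-P, a scaled log2 difference of 9.0 ± 0.35 (the scanner software's error), and ASHGV40051825 had 95.8 and 24983, a difference of 7.94 ± 0.21. In the other direction, ASHGV40043788 had an intensity of 24895 in LoVo-C and 53.6 in LoVo-P, a difference of -8.94 ± 0.22, and ASHGV40009285 had 6180 and 97.1, a difference of -6.08 ± 0.21. The LoVo-C signal of ASHGV40046319 lay near the lowest signal well above background on that array, 14.1 units. The files analysed pair none of these 4 with a gene. Their differences in the authors' processed values were 8.98, 7.99, -8.90 and -6.03.

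A further 1593 probes were well above background on the LoVo-P array alone and 1600 on the LoVo-C array alone. Most of these were dim: the lower bound reached 2-fold for 301 of the first and 239 of the second, and 16-fold for 26 and 16. Under normexp background correction the numbers at 2-fold fell to 69 and 73. The largest bound was at least 1347-fold higher on the LoVo-P array, and at least 87.8-fold higher on the LoVo-C array. The bounds too rest on 1 array per group.

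**Figure D3:**
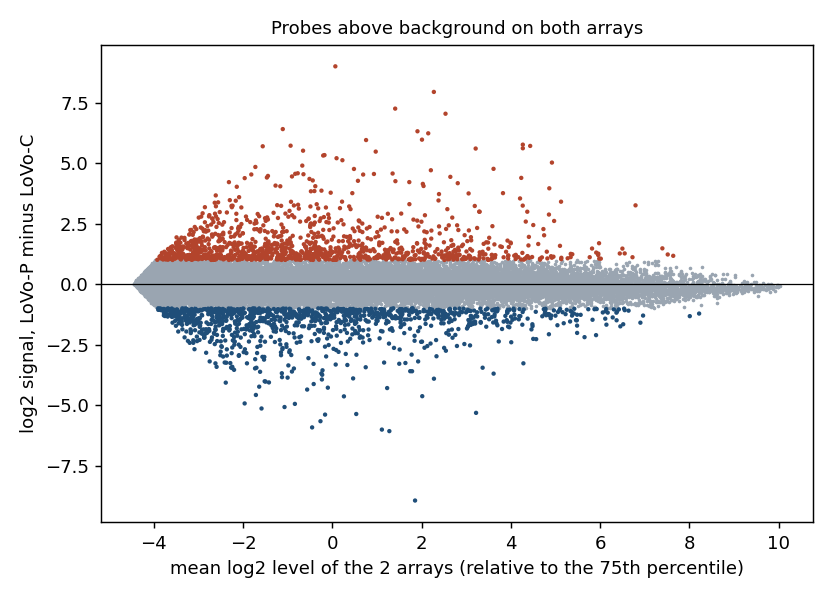
Log2 difference, LoVo-P minus LoVo-C, against the mean log2 level of both arrays for the 37262 probes above background on both. Red points are the 1154 probes at least 2-fold higher on the LoVo-P array and blue points the 1117 at least 2-fold lower; the spread narrows at the brightest levels.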

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

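The tests of array scaling and of a single faulty probe were chosen after the PGK1 result was seen. Signals outside the comparisons were examined in the array's control probes other than the human ones. Of these, 3 were above background on every spot of the LoVo-P array and at least 2-fold higher there than on the LoVo-C array, with spots that did not overlap. The mouse PGK1 probe ending in 5 differed by 1.37 and the rat PGK1 probe ending in 5 by 1.32 on the log2 scale, in the direction of the human PGK1 probes. The control probe ERCC-00104_60, of a set designed for synthetic spike-in RNA, differed by 1.73 after scaling: its intensity was 14.7 units on the LoVo-C array, where 23 of 34 spots were above background, and 51.6 on the LoVo-P array, where all 34 were.

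The higher PGK1 signal in LoVo-P was weighed against technical explanations. Array scaling is argued against by the RefSeq probe's lowest log2 difference over 7 other scalings, corrections and value tables, 1.06. A single faulty probe or spot is argued against by the other PGK1-named probes above background, whose smallest difference was 0.73 on the main scale. Whether the difference goes with PRL-3 overexpression, the derivation of each line, the culture or the RNA preparation cannot be told apart with 1 array per group.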

How the results depend on the processing

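The PGK1 difference stayed between 1.06 and 1.11 under all 7 other scalings, corrections and value tables, and the SD of differences between arrays stayed between 0.44 and 0.70 under 9 alternatives. The numbers of probes at least 2-fold higher and lower (1154 and 1117) moved by more than 1.5 times under 5 alternatives. Normexp gave 601 and 631, partly because its offset shrinks dim differences. Other numbers of probes entered with no filter on dim probes (3100 and 2744) and above the median level (580 and 587). By construction, a 1.5-fold threshold gave 3184 and 3035 and a 4-fold one 266 and 216. Normexp also lowered the one-array probes with a bound of at least 2-fold to 69 and 73. The share of 2-fold calls that were higher stayed between 47.9% and 53% under 9 alternatives; at other thresholds it was 51.2% (1.5-fold), 55.2% (4-fold) and 68.8% (16-fold). With the authors' values 1161 and 1114 probes passed, of which 1138 and 1099 were shared with the main calls. Small negative values turned positive under quantile normalization, loess and the authors' values. Of genes whose spots overlapped, GAPDH, MTX1, EIF3D, PRMT1 and H3-3A did so under all 3, at 0.0436 (GAPDH, authors' values) to 0.146 (PRMT1, authors' values). Of probes whose spots separated the arrays, PFN1 turned to 0.019 and the human GAPDH probe ending in 3 to 0.0495 with quantile normalization. Loess gave 0.093 (PFN1), 0.091 (ACTB), 0.0747 (RPLP1) and 0.11 (that GAPDH probe). The authors' values gave 0.0443 (PFN1), 0.0090 (RPLP1) and 0.067 (that GAPDH probe). Probes this bright had a main-scale median of -0.17. Of 154 values of 18 genes and 4 human control probes under the alternatives, 92 moved by less than the spot spread and 38 moved further without changing sign. Another 24 changed sign, 9 of them of probes whose spots separated the arrays and 15 of probes whose spots overlapped. Subtracting local block medians, chosen after seeing the data, left 1146 and 1099 probes. Leaving out a replicate, the slide as a block, the highest probe per gene and unmatched random lists were not run: there is 1 array per group, probes were not joined to genes, and no list was described. No paired analysis was possible because each group has 1 array. Signal over background limits the 37262 probes at their dim end.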

Other observations

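The tests of scatter near background and of shuffled probe numbers were chosen after the result was seen, and the subtraction of block medians was added after the data were seen. Among the 60 negative control probes, Negative047 was bright on the LoVo-C array and not on the LoVo-P array. It had an intensity of 457 units on the LoVo-C array, with a spot SD of 0.08 on the log2 scale and all 6 spots above background, and was not well above background on any of 6 spots of the LoVo-P array, where it was at least 31.9-fold lower. Negative035 went the other way and was dim, with 16.4 units on the LoVo-P array, where 4 of 6 spots were above background, and 0 of 6 spots above background on the LoVo-C array. The probe ERCC-00062_278 had 5736 units on the LoVo-C array and 3856 on the LoVo-P array, 1.58-fold lower after scaling, while 6 of the 12 ERCC probes were mostly at background on at least 1 array. Over the 6 PGK1 probes above background, the main-scale difference fell with the probe's level without exception, from 1.37 at a mean log2 level of 0.49 to 0.73 at 8.41. The size of this fall depends on the scaling. The probe at 8.41, the human one ending in 3, differed by 0.88 with loess and 0.90 with quantile normalization. Above a level of 8, 2 of 370 probes (0.54%) were at least 2-fold apart, against 6.09% of all probes above background on both arrays.

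Of the 2271 probes at least 2-fold apart, 1167 lay above the median level. Under normexp background correction 951 of these 1167 were still at least 2-fold apart the same way. At the median signal of all probes above that level, the normexp offset leaves a true 2-fold difference at 1.94-fold. Most of these calls could therefore hardly change, which makes this weak evidence against scatter near background. For probes below the median level scatter stays open. There 278 of 1104 were still at least 2-fold apart the same way. At the median signal of all probes below that level, however, the offset alone takes a true 2-fold difference to 1.42-fold. Local offsets over blocks of 24 by 21 spot positions are argued against by the block medians, which ran from -0.30 to 0.12. Subtracting them moved 2509 probes by over 0.1 and gave a count of 2245, with 2163 of the 2271 among them. Whether they follow PRL-3 overexpression or any other difference between 2 separately derived lines stays open with 1 array per group.

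Probes with consecutive design numbers differed together. Over 24459 consecutive pairs above background on both arrays, the rank correlation of their differences was 0.105, and none of 10000 shuffles of the numbers came as high (two-sided permutation p = 0.0001, the smallest they can give; probes are not independent replicates). The correlation fell to 0.079 at a gap of 2 numbers and 0.024 at a gap of 50. In 165 pairs both probes were at least 2-fold apart, 123 the same way and 42 opposite ways, where independent probes would give 45.4 pairs of each kind. Neighbouring spots on the array surface do not account for it: among 18517 pairs lying over 50 rows apart the correlation was 0.103. A hypothesis is that consecutive numbers may mark probes for related or neighbouring transcripts; no biological explanation was tested, because the probes' targets were not analysed here.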
